A study of Mus musculus with 30 samples.

How the data were processed

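The samples were hearts of wild-type, untreated mice at 10 ages (E10.5, E12.5, E14.5, E16.5, E18.5, P1, 1W, 2W, 4W and 8W), with 3 libraries per age. Total RNA was enriched for poly(A) RNA with oligo-T beads before sequencing. The submitters' processing notes name fastp 0.18.0, STAR 2.5.3a and the builds GRCm38 and mm10, without their roles or order. The counting tool, the annotation release and the strand setting are not given in the sources used here, so antisense, overlapping and paralogous genes (Myh6 and Myh7, the globins, mitochondrial pseudogenes) are uncertain. The values were expected counts per gene, deposited by the authors in 1 table for all 30 samples. Of these values, 6.9% were not whole numbers (tolerance 1e-06), and all were rounded before testing.

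The table held 48820 genes, 48058 of which were given a symbol and a place in GRCm38 from GENCODE M21, by gene identifier without its version (40606 had the same version too). Genes without a symbol held 0.23% of the counts. Library totals ranged from 23164987 to 50519512 counts. The choices of tests, lists, named genes and alternatives were made before the data were examined, except where stated.

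Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr (19280 genes kept), scaling by the trimmed mean of M values (TMM) and quasi-likelihood F tests with robust dispersions and Benjamini-Hochberg adjustment. A single fit held all 30 samples as 10 group means, which left 20 residual degrees of freedom. One test covered all ages, and 11 compared pairs of ages: E18.5 against E10.5, P1 against E18.5, 8W against P1 and the other 8 steps between neighbouring ages. Standard errors were taken from the fit as the log2 change divided by the square root of F. CPM values are scaled by TMM factors.

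The 48 gene lists (31 pathways and 17 sets of cell type markers, with at least 3 measured members) were tested with fry from limma 3.58.1 on voom values, 2-sided, adjusted over the lists of a comparison. The tests with camera, with an estimated and with a preset correlation of 0.01, were alternatives. In bulk tissue the cell type lists describe marker levels only. List plots show the mean over members of log2 CPM (prior count 2) centred per gene. One listed gene, Ahsp, was not in the table used.

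Paralog shares were percentages of summed counts, tested by permutation of the F ratio over the ages (100000 resamples, adjusted over the 3 shares). Where a group had no count of a gene, the fold is a lower bound from a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% interval, and all such bounds cover counting error only. The overlap of E18.5 against E10.5 with 8W against P1 was compared with the number for independent lists. The age of the highest mean log2 CPM was counted over genes called across the ages.

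Named genes were drawn from those given by a rule. For E18.5 against E10.5, P1 against E18.5 and 8W against P1, these were the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in the higher group, without overlap between the libraries of the groups and with a symbol that is no gene model name. The same rule gave 2 each way for the other steps. Members of lists with the largest changes and a fixed panel of heart genes were added. Sex-linked transcripts were counted as present from a sum of 10 CPM over 4 genes of the Y chromosome and from 50 CPM of Xist.

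The alternatives were RLE size factors, library size alone, upper quartile factors, no filter, a stricter filter (1 CPM in 3 libraries), mitochondrially encoded and globin genes left out, DESeq2 1.42.0, a replicate block, only the 6 samples of a comparison, and each library left out in turn. For overlaps, shares, peaks and list plots they were a 2-fold minimum, mean log2 ratios, medians over replicates and medians over members. A sex term and protein-coding genes only were added after the data were seen. The sex term was coded 0 for libraries with Xist only, 1 for Y transcripts only and 0.5 for both. The tests were also tested on simulated data. Counts were drawn from a negative binomial model with the overall means and dispersions of the real genes, and known changes were put into 1 group. The changed genes (67 at 1.5-fold, 67 at 2-fold and 66 at 4-fold) were drawn from genes above a minimum mean level. All other genes had the same mean at every age. The simulation thus does not test scaling where most genes change, as they did in the real data. Of the genes raised or lowered 1.5-fold, 80.6%, 83.6% and 73.1% were called in E18.5 against E10.5, P1 against E18.5 and 8W against P1, and 98.5%, 98.5% and 97% of those changed 2-fold, with 6, 9 and 7 false calls among 18546, 18561 and 18502 genes. Figures and shares were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.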

Results

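Gene expression was measured by RNA sequencing of poly(A)-selected RNA from hearts of untreated wild-type mice at 10 ages, with 3 libraries per age and 30 in all. The ages were E10.5, E12.5, E14.5, E16.5 and E18.5 before birth, and postnatal day 1 (P1) and weeks 1, 2, 4 and 8 (1W, 2W, 4W and 8W) after it. Library totals ranged from 23164987 to 50519512 counts. The labels do not say whether the libraries of an age came from separate animals, so the p-values measure only the spread between these samples. Levels are given as CPM (counts scaled to a common library size), mean ± SD (n = 3), and changes as log2(later/earlier) ± SE. A gene rose or fell where its edgeR quasi-likelihood test passed an adjusted p of 0.05, and list tests were made with fry. Values with an estimated or preset correlation came from another test, camera, which compares a list with the other genes. Fry asks only whether the members of the list changed, so the tests ask different questions. The correlation was estimated from all 30 libraries. Counts of list members adjusted over the list alone are given where they differ from the counts over all genes.

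The libraries differed in sex-linked transcripts, in mitochondrially encoded RNA and in small noncoding RNA. Transcripts of the Y chromosome without Xist, the noncoding RNA of the inactive X chromosome, were found in all 3 P1 libraries, and Xist without them in all 3 libraries of 4W and of 8W. All 3 libraries of E10.5 carried both, as did 2 of E12.5 and 2 of E14.5. Pools of animals of both sexes would give this, but the labels do not say whether libraries were pools. The share of mitochondrially encoded RNA in the counts was 3.02% ± 0.14 (SD, n = 3) at E14.5, 6.08% ± 0.83 at P1 and 18.98% ± 0.17 at 8W. Replicate 2 of E10.5 stood apart, with 32231 CPM in Rn7sk, a small nuclear RNA, against 6112.9 and 5666.5 in the other E10.5 libraries. Rn7sk, which has no poly(A) tail, stood at 5666.5 CPM or more in every library. Rpph1, another such RNA, stood at 1437.4 CPM or more. These CPM are without TMM factors. How complete the poly(A) selection was is thus not known.

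The first question was which genes change with age. Of 19280 genes tested, 18053 (93.6%) changed across the 10 ages (edgeR adjusted p under the threshold). E10.5 was the age of the highest mean for 4898 of these genes (27.1%), 8W for 4003 (22.2%), E12.5 for 2186, P1 for 1627 and 4W for 1496. The other ages were 1W with 746, 2W with 884, E14.5 with 808, E16.5 with 860 and E18.5 with 545. With library size alone, the numbers were 3817 at E12.5, 1912 at E14.5, 518 at 2W, 810 at 4W and 1175 at 8W. The leading principal component of all libraries held 61% of the variance and the next ones 11.8% and 4.8%. Between neighbouring ages, the step from E10.5 to E12.5 had the highest number of calls (10675), as the plot of genes changed by comparison shows. The step from E12.5 to E14.5 had 3528 calls, or 6207 with only its 6 samples in the fit, against 4392 for 2W against 1W and 3995 for 4W against 2W fitted that way. Without E12.5 replicate 2 or E14.5 replicate 3, the E14.5 step fell to 2255 or 2222 calls, and without E18.5 replicate 3 the step from E16.5 to E18.5 had 3104 calls in place of 4669.

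**Figure D1:**
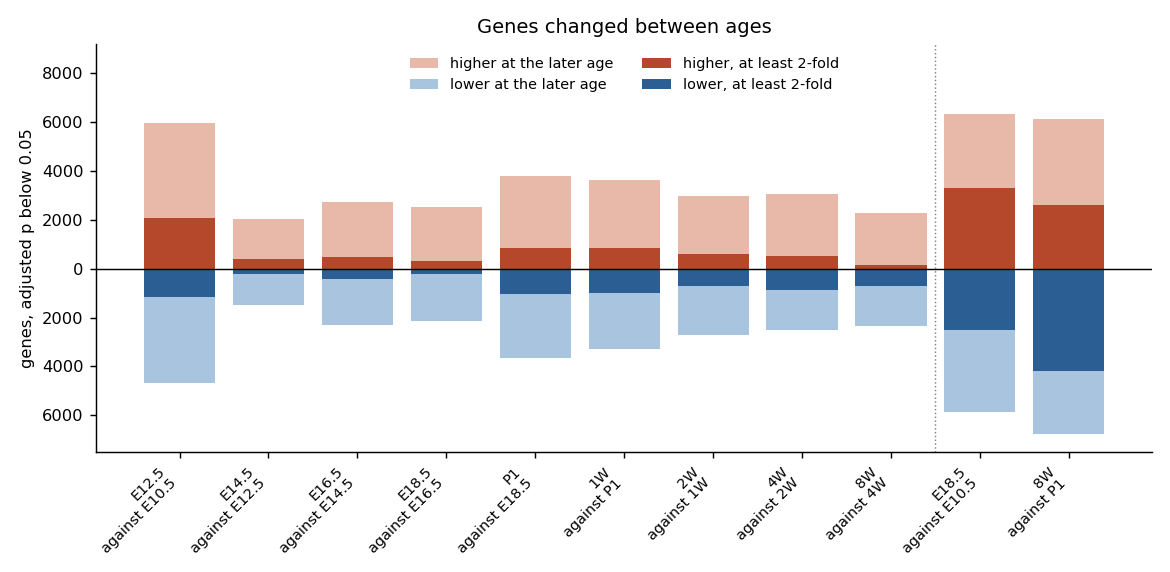
Numbers of genes that rose or fell (edgeR adjusted p under 0.05, vertical axis, number of genes) in each comparison of 2 ages (horizontal axis), with the part of them changed at least 2-fold. P1 against E18.5 had 3808 genes up and 3672 down with the trimmed mean of M values (TMM) as scaling, and 2583 up and 4719 down with library size alone.

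The split between rising and falling genes depended on the scaling in most comparisons. Scaling by library size alone moved the median log2 change of all genes by -0.16 in E18.5 against E10.5, -0.11 in P1 against E18.5 and -0.77 in 8W against P1. The shifts were -0.15 in E16.5 against E14.5, -0.11 in 1W against P1, -0.29 in 2W against 1W, -0.23 in 4W against 2W and -0.15 in 8W against 4W. All changes below are relative to the main scaling, TMM. Rising and falling genes with TMM and with library size alone were 2713 and 2306 against 1508 and 4014 for E16.5 against E14.5, and 2507 and 2162 against 1825 and 2764 for E18.5 against E16.5. They were 3624 and 3274 against 2507 and 4488 for 1W against P1, and 2993 and 2714 against 1134 and 6985 for 2W against 1W. For 4W against 2W they were 3055 and 2514 against 1245 and 5328, or 2378 and 3235 with upper quartile factors. For 8W against 4W they were 2275 and 2328 against 798 and 3763, or 1682 and 2757 with upper quartile factors.

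Paralog shares, which do not depend on scaling between libraries, gave the timing of the switches in transcripts of contractile and oxygen-carrying proteins. The proteins were not measured. Myh6, the alpha myosin heavy chain of the adult mouse heart, made up 34.6% ± 3.35 (SD, n = 3) of Myh6 and Myh7 counts at E10.5, 21.03% ± 0.934 at E16.5, 44.1% ± 0.315 at E18.5, 73.6% ± 3.74 at P1, 98.7% ± 0.624 at 1W and 99.7% ± 0.0495 at 8W. Tnni3, the cardiac troponin I, made up 23.8% ± 1.92 of Tnni1 and Tnni3 counts at E10.5, 49.8% ± 0.257 at E18.5, 72.3% ± 1.87 at 1W and 99.3% ± 0.202 at 2W. The embryonic globins Hba-x, Hbb-y and Hbb-bh1 made up 83.3% ± 3.03 of the counts of 11 globin genes at E10.5, 54.2% ± 2.53 at E12.5, 15.2% ± 2.55 at E14.5 and 0.148% ± 0.0578 at E16.5. None of 166691 globin counts at 2W and none of 184359 at 8W came from them, which allows shares of up to 0.0018% and 0.00163%. Each of the 3 shares differed between ages (permutation test with 100000 resamples, adjusted p = 1e-05, the smallest it can give). Such limits and all intervals given here cover counting error only. Myh6 (chromosome 14, 54941921 to 54966927 in GRCm38) and Myh7 (54970684 to 54994626) lie side by side and share sequence, as do the globins, which leaves the split of reads between them uncertain.

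**Figure D2:**
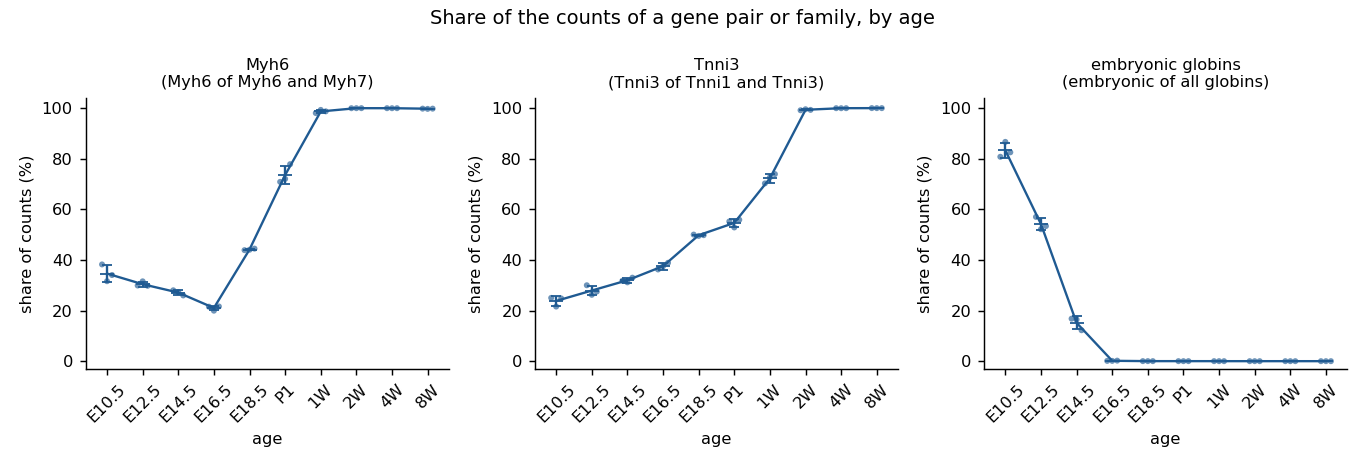
Share of Myh6 in Myh6 and Myh7 counts, of Tnni3 in Tnni1 and Tnni3 counts and of the embryonic globins in all globin counts (vertical axes, percent) at the 10 ages (horizontal axes, equally spaced), with points for libraries and bars for mean ± SD (n = 3). The Myh6 share goes from 21.03% at E16.5 to 98.7% at 1W, and the Tnni3 share passes 99% at 2W.

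E18.5 against E10.5 asked how the heart changed over the part of gestation sampled here. Genes of the adult sarcomere and of fatty acid oxidation and fibroblast markers rose as lists, while RNA-binding genes of the early embryo fell. Macrophage markers were called higher, and embryonic globins and ribosomal protein genes lower, without a call with an estimated correlation. Ckm, the muscle creatine kinase, went from 1.28 ± 0.419 to 1775 ± 80.4 CPM (log2 change 10.46 ± 0.19, edgeR adjusted p = 3.6e-29). Hbb-bh1 went from 3025 ± 1950 to 0.0327 ± 0.0351 CPM, a ratio of 108600 with a 95% counting interval of 37160 to 526600. In all, 6340 genes rose and 5858 fell, 3288 and 2513 of them at least 2-fold.

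The other leading risers included 2 genes without a count at E10.5, Fmo2, a flavin-containing monooxygenase (at least 510.4-fold higher, with a floor of 3 counts over the group), and Agtr2, an angiotensin receptor (at least 488.6-fold). The ratios of the lipid transporter gene Abca8a, the perinatal myosin gene Myh8 and the butyrophilin-like gene Btnl9 were 2226 (761.6 to 10790), 2688 (482.5 to 106200) and 2446 (439.1 to 96620). Below the globins Hbb-y (-13.55 ± 0.51) and Hba-x (-12.43 ± 0.35), the largest falls were in Pklr, the pyruvate kinase of red cells (ratio 541.8, 150 to 4474), in Trim71, a let-7 target (-8.79 ± 0.41), and in Hapln1, which links hyaluronan to proteoglycans (-7.08 ± 0.17). Ckm lies on chromosome 7 (19404776 to 19422841), Trim71 on chromosome 9 (114507133 to 114564369), Hapln1 on chromosome 13 (89539796 to 89611652) and Hbb-bh1 on chromosome 7 (103841637 to 103843164).

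All 16 measured adult sarcomere genes rose (fry adjusted p = 3.4e-21), as did all 12 cardiomyocyte markers (4.6e-20). Examples were Myom2 (9.82 ± 0.26), Casq2 (5.99 ± 0.12), Myh6 (2.67 ± 0.12), Tnni3 (2.24 ± 0.09), Ttn (1.25 ± 0.17) and Actc1 (0.99 ± 0.12). Of 19 calcium handling genes, 14 rose and 2 fell (7.3e-16; adjusted p = 0.053 with an estimated correlation), among them Pln (2.06 ± 0.1), Ryr2 (1.95 ± 0.13) and Atp2a2 (1.56 ± 0.12), the calcium pump of the sarcoplasmic reticulum. The 24 ion channel and gap junction genes gave 18 risers and 3 falls (3.4e-12; adjusted p = 0.16 with an estimated correlation). Fetal sarcomere and cardiac fetal genes split into 6 that rose and 5 that fell of 12, without a call for the list (fry adjusted p = 0.2, 0.05 without E10.5 replicate 2 and 0.047 without 2W replicate 3), and its direction turned with library size alone. Myh7 (2.11 ± 0.22), Tnni1 (0.56 ± 0.15) and Nppa (1.77 ± 0.12) rose, Acta1 fell (-2.05 ± 0.59), and Nppb, a ventricular natriuretic peptide, did not pass (-0.02 ± 0.38). Bmp10, an atrial growth factor, rose by 0.51 ± 0.17.

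Of 30 fatty acid oxidation genes, 27 rose and none fell (fry adjusted p = 5.7e-17), including Acadm (2.05 ± 0.08) and Cpt1b (1.46 ± 0.09), which brings fatty acids into mitochondria. The TCA cycle had 21 risers of 22 (2.8e-16), and the metabolic transcription regulators 13 risers and 3 falls of 17 (3.3e-16), led by Perm1 (6.11 ± 0.14), Ppara (5.52 ± 0.19), Esrra (1.19 ± 0.1) and Ppargc1a (1.11 ± 0.11). Branched-chain amino acid genes rose in 21 of 24 cases (2.3e-11; adjusted p = 0.16 with an estimated correlation), with Bckdhb at 0.99 ± 0.12. Nuclear genes of complex I rose in 20 of 36 cases (2.7e-05) and of complexes III to V in 22 of 35 (4.1e-05), each with adjusted p = 0.52 with an estimated correlation. Their mean centred log2 CPM was -0.59 ± 0.45 (SD, n = 3) and -0.68 ± 0.44 at E10.5, with -0.07 and -0.17 in replicate 2, and -0.06 ± 0.04 and -0.04 ± 0.03 at E18.5. Cox6a2 (1.96 ± 0.11) and Cox7a1 (1.17 ± 0.24), of complexes III to V, rose. The mitochondrially encoded transcripts did not pass (1 rose and 6 fell of 13, 4 adjusted over the list alone, fry adjusted p = 0.066), with 0.73 without E10.5 replicate 2, 0.0082 without E10.5 replicate 3 and 0.028 without E18.5 replicate 3. Glycolysis genes rose in 13 of 20 cases and fell in 4 (8.2e-09; adjusted p = 0.42 with an estimated correlation). The muscle glucose transporter gene Slc2a4 (2.84 ± 0.12), Hk1 (1.25 ± 0.12) and Hk2 (1.01 ± 0.11) rose, whereas the ubiquitous transporter gene Slc2a1 fell (-2.15 ± 0.16) and Ldha stood at 0.02 ± 0.11. Pdk4 (1.28 ± 0.2) and Oxct1 (1.13 ± 0.12) rose, and Bdh1, an enzyme of ketone use, did not pass (-0.13 ± 0.27).

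Growth programmes of the early embryo fell. All 10 genes of the list of early RNA-binding proteins and the let-7 axis fell (fry adjusted p = 1.3e-17), among them Lin28b (-3.68 ± 0.26) and Igf2bp3 (-1.47 ± 0.12). Of 21 imprinted growth genes, 14 fell (16 adjusted over the list alone) and 3 rose (3.5e-13), with H19 at -0.65 ± 0.1 and Cdkn1c, a cell cycle inhibitor, at -2.59 ± 0.16, while Igf2 did not pass (-0.23 ± 0.1). Cytosolic ribosomal protein genes fell in 38 of 39 cases (39 adjusted over the list alone, 2.1e-07; adjusted p = 0.3 with an estimated correlation). The mean centred log2 CPM of these cytosolic ribosomal proteins was 0.94 ± 0.46 (SD, n = 3) at E10.5, with 1.47 in replicate 2, and -0.02 ± 0.06 at E18.5. S phase genes fell in 18 of 24 cases (19 adjusted over the list alone, 9.9e-06; adjusted p = 0.36 with an estimated correlation). G2/M phase genes fell in 8 of 25 (0.045; adjusted p = 0.63 with an estimated correlation), with Ccnb1 at -1.26 ± 0.35, Top2a at -0.9 ± 0.31 and Mki67, which did not pass, at -0.46 ± 0.3. That list call was lost without any 1 of 23 libraries, up to an adjusted p of 0.097 without E18.5 replicate 2. Without 2W replicate 3, which is in neither group, its fry adjusted p was 5.2e-06. Cardiac transcription factors split evenly, 9 up and 9 down of 24 (0.09, 0.0016 without E10.5 replicate 2), and the core factors did not pass, with Gata4 at -0.04 ± 0.07, Nkx2-5 at -0.1 ± 0.1 and Tbx20 at -0.18 ± 0.09. Morphogen signalling genes fell in 15 of 27 cases and rose in 7 (6.5e-09; adjusted p = 0.31 with an estimated correlation).

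Fibroblast markers rose in 11 of 13 cases (fry adjusted p = 2.2e-17) and mural cell markers in 10 of 11 (3.1e-14). Col1a1 (5.25 ± 0.16) and Col3a1 (2.8 ± 0.11), the fibrillar collagens, were in step with 18 risers of 22 extracellular matrix genes (7.4e-17; adjusted p = 0.061 with an estimated correlation). Basement membrane genes rose in 12 of 14 cases (5.7e-13; adjusted p = 0.17 with an estimated correlation) and endothelial markers in 12 of 14 (5.6e-14; adjusted p = 0.061 with an estimated correlation). All 12 macrophage markers (7.4e-13; adjusted p = 0.089 with an estimated correlation), all 20 interferon response genes (4.7e-11; adjusted p = 0.14 with an estimated correlation) and 15 of 16 antigen presentation genes (6e-08; adjusted p = 0.3 with an estimated correlation) rose. Endocardial and valve markers fell in 7 of 10 cases (1.9e-13; adjusted p = 0.17 with an estimated correlation), and erythroid markers in 7 of 13 (4.7e-05; adjusted p = 0.44 with an estimated correlation). The 3 embryonic globins fell (1.6e-10; adjusted p = 0.17 with an estimated correlation). Epicardial markers gave 3 up and 5 down of 11 without a call (0.82). Their test and mean (0.58) pointed up and their median (-0.33) down, and the direction turned with library size alone, with upper quartile factors and without E10.5 replicate 2 (0.014) or 3 (0.93). Lymphocyte markers rose in 4 of 9 cases and fell in 1 (2e-04; adjusted p = 0.59 with an estimated correlation), and liver markers rose in 6 of 9 (0.0052; adjusted p = 0.64 with an estimated correlation). Levels of members of these 2 lists were low at E18.5, with Rag1 at 0.213, Ms4a1 at 0.164, Fgb at 0.618 and Alb at 5.17 CPM.

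Leaving out E10.5 replicate 2 ended the call of Bmp10 in E18.5 against E10.5 (edgeR adjusted p = 0.096) and made calls of Ldha in E18.5 against E10.5 (0.016), Tbx20 in E18.5 against E10.5 (0.018) and Igf2 in E18.5 against E10.5 (1.7e-05). Igf2 in E18.5 against E10.5 also passed without 2W replicate 2 (0.042) or 3 (0.049), and Mki67 in E18.5 against E10.5 without 2W replicate 3 (0.0029).

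P1 against E18.5 asked what changed across birth. Fatty acid oxidation genes rose as a list, and the glucose transporter gene Slc2a1 and the lactate exporter gene Slc16a3 fell. All 49 S phase and G2/M phase genes fell, without a list call with an estimated correlation. Pdk4, which shuts off pyruvate dehydrogenase, rose from 32.2 ± 1.66 to 418.2 ± 99.8 CPM (log2 change 3.7 ± 0.21, edgeR adjusted p = 3.5e-12). Slc16a3 fell from 60.3 ± 1.95 to 6.13 ± 0.591 CPM (-3.3 ± 0.15, 3.4e-16). In all, 3808 genes rose and 3672 fell, 850 and 1032 of them at least 2-fold, and 2583 rose and 4719 fell with scaling by library size alone.

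Strong risers included Ucp3, a mitochondrial carrier of muscle induced by fatty acids (7.53 ± 0.4), the mitochondrial carrier gene Slc25a34 (4.25 ± 0.21), Angptl4, an inhibitor of lipoprotein lipase (3.73 ± 0.21), and the stearoyl-CoA desaturase gene Scd4 (3.54 ± 0.29). Behind Slc16a3, the largest falls were in the cyclin gene Ccne2 (-3.09 ± 0.29), the cohesin acetyltransferase gene Esco2 (-2.83 ± 0.37), the histone genes Hist2h3c2 (-2.82 ± 0.41) and Hist1h2ah (-2.67 ± 0.41), and the replication licensing gene Cdc6 (-2.76 ± 0.29). Their edgeR adjusted p lay between 8.9e-14 and 2.2e-05. Most histone transcripts have no poly(A) tail, so counts of the histone genes also depend on how complete the poly(A) selection was. Ucp3 lies on chromosome 7 (100472990 to 100486432), Pdk4 on chromosome 6 (5483351 to 5496309), Slc16a3 on chromosome 11 (120948480 to 120960868) and Ccne2 on chromosome 4 (11191351 to 11204779).

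All 24 S phase genes fell (fry adjusted p = 1.2e-07; adjusted p = 0.11 with an estimated correlation), and so did all 25 G2/M phase genes (2.2e-06; adjusted p = 0.18 with an estimated correlation). Top2a (-2.27 ± 0.33), Mki67 (-1.65 ± 0.31) and Ccnb1 (-1.52 ± 0.36) were among them. All 3 P1 libraries and 1 of the 3 E18.5 libraries carried Y transcripts without Xist, and 48 of these 49 genes fell with a term for sex-linked transcripts in the model. Cell cycle exit genes fell in 7 of 15 cases and rose in 5 (fry adjusted p = 0.0026). That p was 0.19 without P1 replicate 3 and 1.1e-05 without 2W replicate 3, and the adjusted p with an estimated correlation was 0.51.

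**Figure D3:**
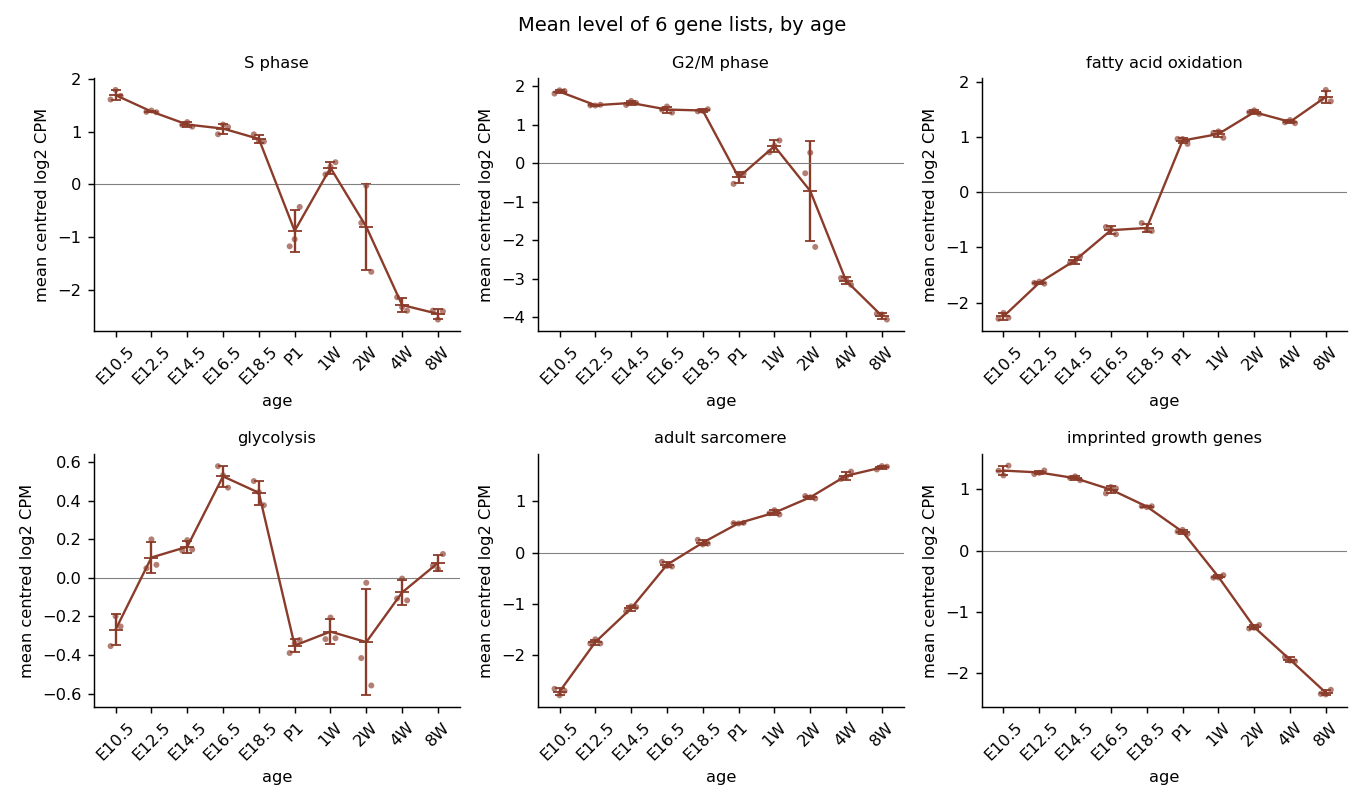
Mean over list members of log2 CPM centred per gene (vertical axes, log2) at the 10 ages (horizontal axes, equally spaced), for S phase, G2/M phase, fatty acid oxidation, glycolysis, adult sarcomere and imprinted growth genes, with points for libraries and bars for mean ± SD (n = 3). At P1 all 24 S phase and all 25 G2/M phase genes were lower than at E18.5, and 29 of 30 fatty acid oxidation genes were higher.

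Of the 30 fatty acid oxidation genes, 29 rose (fry adjusted p = 1.5e-15), Cpt1b by 1.12 ± 0.09 and Acadm by 0.5 ± 0.08. Glycolysis genes fell in 16 of 20 cases and rose in 3 (1.7e-07; adjusted p = 0.22 with an estimated correlation), with Slc2a1 at -2.04 ± 0.16, Hk2 at -1.31 ± 0.11, Ldha at -1.15 ± 0.11 and Hk1 at -0.39 ± 0.12. Slc2a4, which is not on that list, did not pass (-0.02 ± 0.1). Hypoxia response genes fell in 12 of 18 cases (13 adjusted over the list alone) and none rose (2.5e-13). The ketone body list was called higher, with 3 risers (5 adjusted over the list alone) and 2 falls of 7 (6.8e-06; adjusted p = 0.51 with an estimated correlation), and the falls were in Oxct1 (-1.18 ± 0.12) and Bdh1 (-1.31 ± 0.3). TCA cycle genes rose in 9 of 22 cases (0.0014; adjusted p = 0.51 with an estimated correlation), a call that ended with library size alone (0.22). Metabolic transcription regulators rose in 11 of 17 cases and fell in 2 (3 adjusted over the list alone, 9e-07; adjusted p = 0.11 with an estimated correlation), with Ppargc1a at 0.29 ± 0.11, Esrra at 0.32 ± 0.1 and Ppara at -0.43 ± 0.13. Complex I (6 up and 2 down of 36, fry adjusted p = 0.93) and complexes III to V (7 up and 3 down of 35, 0.74) did not pass, and the direction of both turned with library size alone. In complex I the median (-0.08) and the mean (-0.02) lay below 0 and the test above it, except without E10.5 replicate 2 (0.95), P1 replicate 2 (0.94) or P1 replicate 3 (0.95). Bckdhb (-0.22 ± 0.12), Cox7a1 (-0.28 ± 0.23) and Cox6a2 (-0.07 ± 0.11) did not pass.

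**Figure D4:**
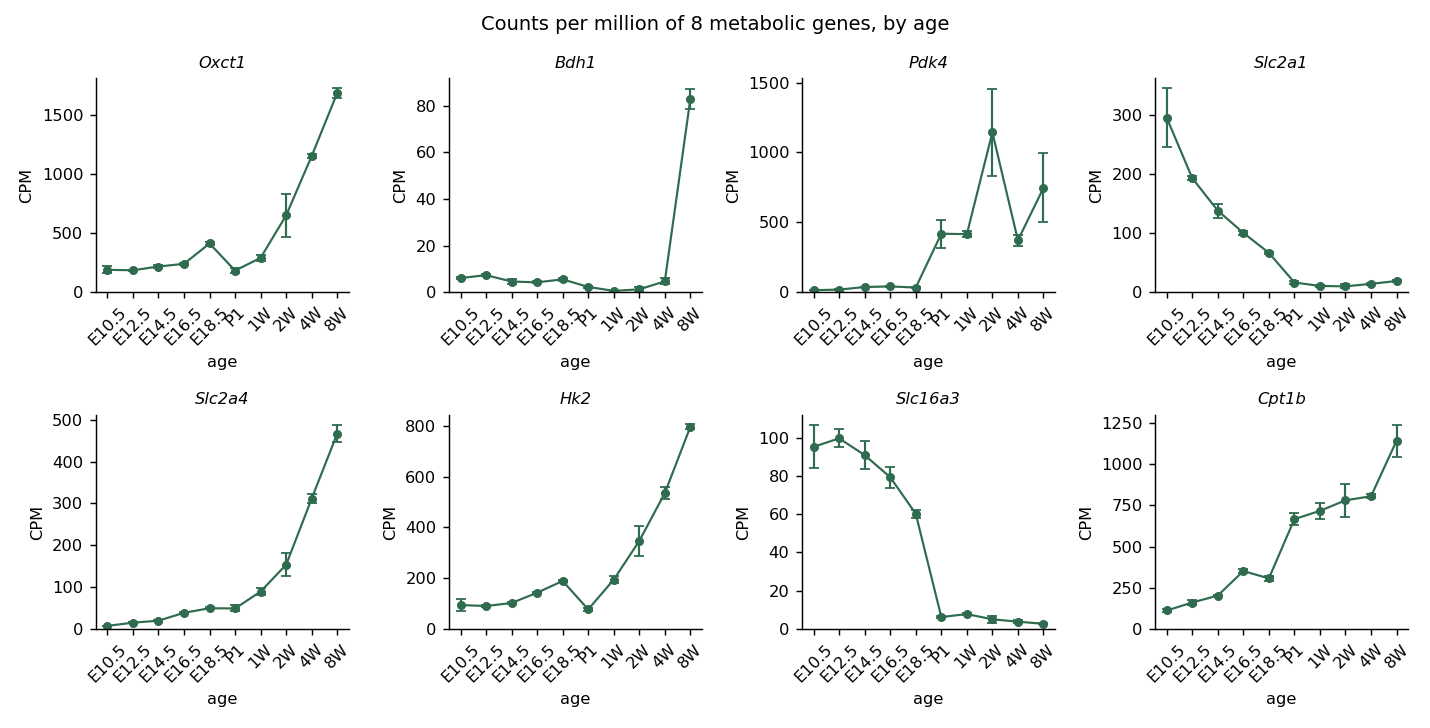
Levels of 8 metabolic genes (vertical axes, CPM from 0) at the 10 ages (horizontal axes, equally spaced), as mean ± SD (n = 3). Pdk4 rises from 32.2 CPM at E18.5 to 418.2 CPM at P1, whereas Oxct1 and Bdh1 are highest at 8W (1688 and 83.0 CPM).

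Transcripts that respond to hormones, to the clock and to stimulation rose as well. Glucocorticoid response genes rose in 15 of 16 cases (fry adjusted p = 9.3e-12) and circadian clock genes in 12 of 18, with 1 that fell (1.7e-18). Klf9 (2.53 ± 0.11) was among the former and Per1 (2.37 ± 0.12), a clock gene with glucocorticoid response elements, is on both lists. Immediate early genes rose in 11 of 19 cases (12 adjusted over the list alone) and 1 fell (2 adjusted over the list alone, 0.00023; adjusted p = 0.41 with an estimated correlation). Of these, the glucocorticoid response and circadian clock lists were called lower from P1 to 1W, as given below. All 3 lists were also called higher in E18.5 against E10.5. That does not show whether the step from E18.5 to P1 was particular to birth. There, circadian clock genes rose in 16 of 18 cases and 1 fell (fry adjusted p = 2.8e-17). Glucocorticoid response genes rose in 13 of 16 and 1 fell (3.4e-08; adjusted p = 0.29 with an estimated correlation). Immediate early genes rose in 13 of 19 (3.1e-06; adjusted p = 0.36 with an estimated correlation). The sampling hour of the hearts is not given in the sources used here.

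Imprinted growth genes fell in 13 of 21 cases (14 adjusted over the list alone) and none rose (fry adjusted p = 3.6e-10), with Igf2 at -0.34 ± 0.1 and H19 at -0.26 ± 0.1. Lin28b (0.29 ± 0.27) and Igf2bp3 (-0.24 ± 0.12) did not pass. Adult sarcomere genes rose in 8 of 16 cases (9 adjusted over the list alone, 1.7e-07; adjusted p = 0.11 with an estimated correlation). Myh6 (1.08 ± 0.11), Atp2a2 (0.88 ± 0.12), Pln (0.83 ± 0.1), Ryr2 (0.71 ± 0.12) and Tnni3 (0.39 ± 0.08) rose and Myh7 fell (-0.74 ± 0.21). No call was made for Ttn (0.06 ± 0.16), Actc1 (-0.07 ± 0.11), Tnni1 (0.11 ± 0.15), Acta1 (-0.32 ± 0.58) or Nppb (0.42 ± 0.38). Nppa (0.32 ± 0.12) and Gata4 (0.28 ± 0.07) rose, Bmp10 (-0.63 ± 0.17) and Hapln1 (-0.88 ± 0.19) fell, and Nkx2-5 (-0.07 ± 0.1) and Tbx20 (0.02 ± 0.09) did not pass. Col1a1 (-0.2 ± 0.13) and Col3a1 (0.13 ± 0.1) did not pass either. Their list, the extracellular matrix genes, had 2 risers and 5 falls of 22 without a call (0.19), but passed without P1 replicate 2 (0.013) and with library size alone (0.016).

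Among markers of other cells, granulocyte markers rose in 7 of 8 cases (fry adjusted p = 6.7e-09), with S100a9 going from 0.802 ± 0.184 to 4.87 ± 1.28 CPM. Adipocyte markers rose in 8 of 10 cases (9 adjusted over the list alone, 1.1e-07; adjusted p = 0.11 with an estimated correlation), and macrophage markers in 7 of 12 (0.0017; adjusted p = 0.51 with an estimated correlation). Schwann and neuronal markers (1 up and 3 down of 12, 0.18) gave no list call.

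Several small changes rested on single libraries. The call of Nppa in P1 against E18.5 ended without E18.5 replicate 2 (edgeR adjusted p = 0.081) or 3 (0.12) or P1 replicate 1 (0.2) or 2 (0.06), and that of Ppargc1a in P1 against E18.5 without E18.5 replicate 1 (0.13) or 2 (0.078) or P1 replicate 1 (0.12) or 3 (0.066). H19 in P1 against E18.5 did not pass without E18.5 replicate 1 (0.12) or 2 (0.073) or P1 replicate 1 (0.13), Esrra in P1 against E18.5 without E18.5 replicate 3 (0.066), Ppara in P1 against E18.5 without P1 replicate 1 (0.054) and Hk1 in P1 against E18.5 without P1 replicate 2 (0.064). Conversely, Lin28b in P1 against E18.5 (0.03) and Col1a1 in P1 against E18.5 (0.031) passed without P1 replicate 2, Igf2bp3 in P1 against E18.5 without 4W replicate 1 (0.022) and Cox7a1 in P1 against E18.5 without E10.5 replicate 2 (0.017). With library size alone, Nppa (0.21), Ppargc1a (0.17), Esrra (0.2) and Gata4 (0.16) did not pass.

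8W against P1 asked how the newborn heart differed from the adult one. Genes of the adult sarcomere, the TCA cycle and branched-chain amino acid catabolism rose as lists, as did Oxct1 and Bdh1 of ketone use, while imprinted growth genes and the fetal isoform genes Tnni1 and Myh7 fell. Cell cycle and matrix genes were called lower, without a list call with an estimated correlation. Oxct1, the enzyme that activates ketone bodies for use, rose from 182.1 ± 18.0 to 1688 ± 44.9 CPM (log2 change 3.21 ± 0.13, edgeR adjusted p = 4.1e-20). Tnni1, the slow skeletal troponin I of the fetal heart, fell from 1315 ± 98.8 to 1.12 ± 0.329 CPM (-10.18 ± 0.24, 6.5e-23). With TMM, 6123 genes rose and 6768 fell, 2619 and 4200 of them at least 2-fold, against 2224 and 12578 with library size alone and 4884 and 8241 with upper quartile factors, which moved the median log2 change of all genes by -0.19. Restricting libraries and tests to protein-coding genes moved that median by -0.11.

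The leading risers were Scn4b, a sodium channel subunit (8.37 ± 0.62), the phospholipid enzyme gene Hrasls (7.56 ± 0.35), Xist (7.17 ± 3.09), the macrophage lectin gene Mgl2 (6.82 ± 0.45), the chemokine gene Cxcl14 (6.77 ± 0.47) and the hemicentin gene Hmcn2 (6.73 ± 0.22). Apart from Tnni1, the leading falls were in genes of the Y chromosome without a count at 8W, Ddx3y (at least 1247-fold lower), Kdm5d (at least 1062-fold), Eif2s3y (at least 942.9-fold) and Uty (at least 790.2-fold), and in Agtr2 (ratio 889.9, 159.7 to 35150). All P1 libraries carried Y transcripts and all 8W libraries Xist, and none of these 5 sex-linked genes passed with a term for sex-linked transcripts, with Xist at -2.85 (edgeR adjusted p = 0.074). Each of the 5 calls was close to the threshold (edgeR adjusted p between 0.034 and 0.047) and ended without any 1 of the 8W libraries. The P1 and 8W libraries did not overlap, though. Without TMM factors, the 4 genes of the Y chromosome summed to 167.56 to 182.54 CPM at P1 and 0 at 8W. Xist stood at 1.3 to 1.84 CPM at P1 and 122.18 to 154.27 at 8W. The fit held all 30 samples. In it, E16.5, E18.5, 1W and 2W each mixed libraries with Xist only and with Y transcripts only. The adjusted p thus do not measure the spread within P1 and 8W alone. Xist in 8W against P1 had an adjusted p of 0.062, 0.065 and 0.06 without 8W replicate 1, 2 and 3, and 0.11 without any 1 of the P1 libraries, and did not pass without any 1 of 21 libraries of the series. Ddx3y in 8W against P1 had 0.075, 0.08 and 0.079 without an 8W library, Kdm5d in 8W against P1 0.079, 0.085 and 0.084, Eif2s3y in 8W against P1 0.076, 0.082 and 0.08, and Uty in 8W against P1 0.085, 0.091 and 0.09. The calls also ended without P1 replicate 3 for Ddx3y (0.051), replicate 1 or 2 for Kdm5d (0.054 and 0.055), replicate 1 for Eif2s3y (0.053) and any of the 3 for Uty (0.058, 0.055 and 0.06). Scn4b lies on chromosome 9 (45138395 to 45154152), Tnni1 on chromosome 1 (135779434 to 135810989) and Xist on the X chromosome (103460366 to 103483254).

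Myh7 fell (-5.75 ± 0.26), and the fetal sarcomere list as a whole had 5 falls and 2 risers of 12 (fry adjusted p = 8.5e-08; adjusted p = 0.47 with an estimated correlation), with a median of 0.05 against a mean of -1.27. All 16 adult sarcomere genes (7.3e-17) and all 12 cardiomyocyte markers (3.1e-17) rose, including Tcap (2.55 ± 0.11), Tnni3 (1.62 ± 0.08), Myh6 (1.36 ± 0.11), Ttn (0.99 ± 0.17) and Actc1 (0.76 ± 0.12). Calcium handling genes rose in 15 of 19 cases and fell in 2 (1.1e-12, 0.31 with library size alone; adjusted p = 0.098 with an estimated correlation), with Atp2a2 at 1.88 ± 0.12, Pln at 1.5 ± 0.1 and Ryr2 at 1.23 ± 0.12. Nppa (0.4 ± 0.12), Acta1 (3.28 ± 0.62) and Bmp10 (0.98 ± 0.17) rose and Nppb did not pass (0.12 ± 0.38). Atrial markers rose in 5 of 10 cases and fell in 2 (1.3e-06; adjusted p = 0.47 with an estimated correlation), a direction that turned with library size alone (0.00016).

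Energy metabolism rose over several pathways. All 22 TCA cycle genes (fry adjusted p = 4.7e-17), 23 of 24 branched-chain amino acid genes (7.6e-17) and 15 of 17 metabolic transcription regulators (3e-18, 2 fell) rose, among them Bckdhb (1.28 ± 0.12), Rxrg (5.76 ± 0.2), Ppara (2.53 ± 0.13), Esrra (1.21 ± 0.1) and Ppargc1a (0.93 ± 0.11). Complex I genes rose in 35 of 36 cases (3.3e-09; adjusted p = 0.28 with an estimated correlation), complex III to V genes in 34 of 35 (8.3e-09; adjusted p = 0.3 with an estimated correlation), and all 13 mitochondrially encoded transcripts (5.2e-14; adjusted p = 0.098 with an estimated correlation). Cox7a1 rose by 2.84 ± 0.24 and Cox6a2 by 1.83 ± 0.11. Fatty acid oxidation genes rose in 25 of 30 cases (26 adjusted over the list alone) and fell in 4 (5.2e-14; adjusted p = 0.098 with an estimated correlation), with Acadm at 1.76 ± 0.08, Pdk4 at 0.83 ± 0.19 and Cpt1b at 0.78 ± 0.09. The ketone body list had 5 risers and 2 falls of 7 (9.7e-19; adjusted p = 0.061 with an estimated correlation). Bdh1 rose by 5.23 ± 0.3. Glycolysis genes rose in 13 of 20 cases and fell in 4 (2.6e-08; adjusted p = 0.47 with an estimated correlation), a direction that turned with library size alone (0.71). Slc2a4 (3.27 ± 0.11), Hk2 (3.38 ± 0.12) and Ldha (0.63 ± 0.11) rose, and Slc2a1 (0.22 ± 0.17) and Hk1 (0.09 ± 0.12) did not pass. Antioxidant genes rose in 14 of 19 cases (15 adjusted over the list alone) and fell in 2 (3.3e-13, 0.4 with library size alone; adjusted p = 0.098 with an estimated correlation), and hypoxia response genes in 11 of 18 (12 adjusted over the list alone) with 2 that fell (2.4e-16).

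Growth genes fell further. Of 21 imprinted growth genes, 18 fell and 2 rose (fry adjusted p = 1.1e-23), among them H19 (-5.97 ± 0.12) and the growth factor Igf2 (-4.71 ± 0.12). The early RNA-binding list had 7 falls and 1 riser of 10 (2.1e-08; adjusted p = 0.31 with an estimated correlation), with Igf2bp3 at -6.04 ± 0.2 and Lin28b at -3.5 ± 0.41. G2/M phase genes fell in 24 of 25 cases (3.4e-05; adjusted p = 0.45 with an estimated correlation) and S phase genes in 19 of 24 (0.00041; adjusted p = 0.47 with an estimated correlation), with Ccnb1 at -5.37 ± 0.58, Top2a at -3.61 ± 0.38 and Mki67 at -3.39 ± 0.36. Ribosomal protein genes fell in 33 of 39 cases (35 adjusted over the list alone) and rose in 1 (0.00069; adjusted p = 0.52 with an estimated correlation). Cardiac transcription factors fell in 10 of 24 cases and rose in 5 (0.00041; adjusted p = 0.57 with an estimated correlation), with Tbx20 at -0.94 ± 0.1, while Gata4 (-0.15 ± 0.07) and Nkx2-5 (0.18 ± 0.1) did not pass. Muscle splicing factors, 5 up and 4 down of 16, gave no call (0.092), but passed without E10.5 replicate 2 (0.027), P1 replicate 3 (0.03) or 2W replicate 2 (0.041). Their test pointed up while median (-0.05) and mean (-0.15) lay below 0, and the direction turned with library size alone and with upper quartile factors.

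Of 22 extracellular matrix genes, 18 fell and 3 rose (fry adjusted p = 3.1e-14; adjusted p = 0.098 with an estimated correlation), with Col1a1 at -1.98 ± 0.14, Col3a1 at -1.82 ± 0.1, which had risen before birth, and Hapln1 at -2.54 ± 0.31, which had fallen. Endocardial and valve markers fell in 8 of 10 cases (9e-17), and epicardial markers in 10 of 11 (4e-07; adjusted p = 0.31 with an estimated correlation). Fibroblast markers rose in 6 of 13 cases and fell in 5 (0.00089; adjusted p = 0.82 with an estimated correlation), and mural cell markers rose in 6 of 11 and fell in 3 (8.9e-07; adjusted p = 0.52 with an estimated correlation), and both directions turned with library size alone. Endothelial markers, 4 up and 7 down of 14, gave no call (0.59), and their direction turned without E10.5 replicate 3 (0.76) or P1 replicate 2 (0.97). Lung epithelial markers gave none either (1 down of 5, 0.072). Antigen presentation genes rose in 15 of 16 cases (3.2e-11; adjusted p = 0.15 with an estimated correlation), led by the class II gene Cd74 (5.4 ± 0.23), and macrophage markers in 8 of 12 (2.8e-09; adjusted p = 0.31 with an estimated correlation). Skeletal muscle markers fell in 5 of 9 cases (1.6e-05; adjusted p = 0.45 with an estimated correlation) and granulocyte markers in 6 of 8 (7 adjusted over the list alone, 5.6e-08; adjusted p = 0.17 with an estimated correlation).

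With library size alone, Nppa was called lower at 8W (-0.37), and no call was left for Actc1 (-0.01), Ttn (0.21), Ldha (-0.14), Cpt1b (0), Pdk4 (0.06), Ppargc1a (0.16) and Bmp10 (0.21). Slc2a1 (-0.56, edgeR adjusted p = 0.0052), Hk1 (-0.69, 2.6e-05) and Nkx2-5 (-0.59, 1.6e-06) were called lower with it. Gata4 in 8W against P1 passed without E10.5 replicate 2 (edgeR adjusted p = 0.044) and Nkx2-5 in 8W against P1 without 8W replicate 2 (0.045).

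The changes before and after birth, in E18.5 against E10.5 and 8W against P1, share no library. Of the genes tested, 3141 rose in both, against 2013 for independent lists (odds ratio 3.279), and 2639 fell in both, against 2056 (1.845). Fewer went opposite ways, with 1596 that rose and then fell, against 2226 (0.5053), and 1305 that fell and then rose, against 1860 (0.5119). Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.18 and a Spearman correlation of 0.263. The 16 adult sarcomere genes were among those that rose in both, and the collagens Col1a1 and Col3a1 among those that rose and then fell. P1 against E18.5 shares libraries with both of these comparisons and was left out of this count. With library size alone, 1259 genes rose in both, 5395 fell in both, 2799 rose and then fell, and 377 fell and then rose. Far more genes fell than rose in 8W against P1 with that scaling, so the numbers for independent lists differ from those above. They were not computed, and these counts cannot be read as above or below them.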

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

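The sex term and the restriction to protein-coding genes only were chosen after seeing the data. The counts of called genes stayed within 1.5 times under every scaling, filter and test, with 6229 to 8172 calls in P1 against E18.5, 11315 to 12504 in E18.5 against E10.5 and 12143 to 13350 in 8W against P1 without 1 library. Exceptions were E14.5 against E12.5 (3528 calls, 6207 with only its 6 samples, 2222 to 4579 without 1 library) and E18.5 against E16.5 (4669, 3104 to 5619 without 1 library). With an estimated correlation 10, 6 and 8 of 48 lists passed in E18.5 against E10.5, P1 against E18.5 and 8W against P1, in place of 42, 29 and 42, and 26 passed in 8W against P1 with the preset correlation. For the changes before and after birth, library size alone gave 1259 genes up in both, 5395 down in both, 2799 up then down and 377 down then up, and a 2-fold minimum 984, 929, 606 and 164. The numbers for independent lists under these settings were not computed, so these counts cannot be read as above or below them. Across genes, the changes before and after birth had a correlation of 0.173 with library size alone. It was 0.152 with protein-coding genes only and 0.148 to 0.186 without 1 library. Peaks with library size alone were 3817 at E12.5, 1912 at E14.5, 518 at 2W, 810 at 4W and 1175 at 8W. List directions turned with library size alone (adjusted p) in E18.5 against E10.5 for fetal sarcomere (0.46), antioxidant (0.22) and epicardial genes (0.76), in P1 against E18.5 for complex I (0.33), complexes III to V (0.48), cardiac transcription factors (0.75), ribosomal proteins (0.31), splicing factors (0.17), atrial (0.45) and mural markers (0.4), and in 8W against P1 for glycolysis (0.71), splicing factors (1.4e-08), glucocorticoid response (0.00027), atrial (0.00016), fibroblast (4.2e-05), mural (0.0079), lymphocyte (0.64) and adipocyte markers (0.28). They turned with protein-coding genes only for epicardial markers in E18.5 against E10.5 (0.75), complex I (0.99), ribosomal proteins (0.95) and splicing factors (0.84) in P1 against E18.5 and splicing factors in 8W against P1 (0.78). Estimated and preset correlations turned antioxidant genes (0.83 and 0.66) and epicardial markers (0.86 and 0.71) in E18.5 against E10.5. No filter turned skeletal muscle (0.81) and lung markers (0.15) there and lung markers in P1 against E18.5 (0.69). Only 6 samples turned complex I in P1 against E18.5 (0.79) and endothelial markers in 8W against P1 (0.89), and the sex term ribosomal proteins in P1 against E18.5 (1). Without 1 library, the adjusted p of lists that turned ranged, in E18.5 against E10.5, over 1.2e-05 to 0.97 for cell cycle exit, 0.014 to 0.93 for epicardial and 0.024 to 0.95 for lung markers. In P1 against E18.5 the ranges were 0.79 to 1 for complex I, 0.78 to 0.99 for ribosomal proteins, 0.43 to 0.99 for splicing factors, 0.022 to 0.94 for fibroblast, 0.24 to 0.92 for mural, 0.52 to 0.96 for epicardial, 0.15 to 1 for lung and 0.028 to 0.86 for liver markers, and in 8W against P1 0.32 to 0.97 for endothelial and 0.07 to 0.92 for liver markers. Log2 changes that turned with library size alone were Nppa (-0.37), Nppb (-0.65), Actc1 (-0.01), Slc2a1 (-0.56), Hk1 (-0.69), Ldha (-0.14) and Nkx2-5 (-0.59) in 8W against P1, Tnni1 (-0.01), Ttn (-0.06) and Tbx20 (-0.1) in P1 against E18.5, and Ldha (-0.12) in E18.5 against E10.5. Ldha there was also at -0.01 with RLE, the strict filter and DESeq2 and at -0.05 with upper quartile factors and protein-coding genes only. Upper quartile factors gave Nppb -0.07, Hk1 -0.11 and Nkx2-5 -0.02 in 8W against P1, protein-coding genes only Hk1 -0.02 there and Tbx20 0 in P1 against E18.5, the sex term Xist -2.85 and Nppb -0.15 in 8W against P1, and no filter Nppb 0.01 in E18.5 against E10.5. Without 1 library, ranges were Nppb -0.22 to 0.53, Ldha -0.1 to 0.24 and Nkx2-5 -0.17 to 0.04 in E18.5 against E10.5. They were Actc1 -0.17 to 0.01, Ttn -0.01 to 0.16, Slc2a4 -0.14 to 0.07, Nkx2-5 -0.15 to 0.03, Tbx20 -0.15 to 0.13 and Col3a1 -0.01 to 0.21 in P1 against E18.5, and Nppb -0.16 to 0.37 in 8W against P1. The replicate numbers do not pair the samples (2 of 33 correlations of the same number were above 0.1), and the replicate block gave 12238, 7644 and 12948 calls in the 3 main comparisons, Nppb at 0.06 in E18.5 against E10.5 and an opposite direction of splicing factors in P1 against E18.5 (0.95). For all of these changes, the cause was not tested. Depth, from 23164987 to 50519512 counts, limits folds of genes with few counts in 1 group, which are bounds or wide ratios.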

Other observations

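Immediate early genes peaked at 4W. Of 19, 12 rose from 2W to 4W (14 adjusted over the list alone, 1 fell over the list alone, fry adjusted p = 8.2e-07; adjusted p = 0.07 with an estimated correlation) and 11 fell from 4W to 8W, with 1 riser (12 and 2 adjusted over the list alone, 8.3e-06; adjusted p = 0.058 with an estimated correlation). Fos, a transcription factor induced within minutes of stimulation, stood at 4.69 ± 1.62 (SD, n = 3), 50.3 ± 24.8 and 5.17 ± 0.729 CPM at 2W, 4W and 8W. Glucocorticoid response genes, which rose at P1, fell in 11 of 16 cases from P1 to 1W, with 1 riser (5.9e-09; adjusted p = 0.076 with an estimated correlation), and circadian clock genes in 11 of 18, with 1 riser (12 and 3 adjusted over the list alone, 2.1e-13). Per1 stood at 37.1 CPM at E18.5, 191.3 ± 16.7 at P1 and 22.2 ± 1.73 at 1W. Granulocyte markers fell in 5 of 8 cases at 1W (1.8e-07; adjusted p = 0.055 with an estimated correlation), S100a9 to 1.87 ± 0.412 CPM.

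Scgb3a1 and Scgb3a2, secretoglobins of airway epithelium, were found at P1 with an SD above the mean (14.8 ± 25.2 and 12.7 ± 22.0 CPM) and without a count at 1W. Both calls ended without P1 replicate 1, where Scgb3a1 in 1W against P1 had an edgeR adjusted p of 0.28 and Scgb3a2 in 1W against P1 of 0.74.

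Groupings of the libraries by chance were compared with the real ones. For the test across the 10 ages, 1 of 100 groupings, the real one, called as many genes (18053, highest other 3075). Other groupings mix ages within a group, so fewer calls follow from any difference shared by the libraries of an age. Age is thus not told apart from anything else that those libraries share. For each pair of ages, 1 of 10 splits of its 6 libraries, the real one, called as many genes, and the splits are too few to decide. The highest other numbers of genes were 0 in E18.5 against E10.5 (12198 in the real one), 5 in P1 against E18.5 (7480), 3 in 8W against P1 (12891), 19 in E12.5 against E10.5 (10675), 1 in E14.5 against E12.5 (3528), 0 in E16.5 against E14.5 (5019), 0 in E18.5 against E16.5 (4669), 1 in 1W against P1 (6898), 6 in 2W against 1W (5707), 189 in 4W against 2W (5569) and 1 in 8W against 4W (4603). For lists they were 3 (42), 2 (29) and 1 (42) in the 3 main comparisons.

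The test of dilution below was chosen only after its result was seen. S phase and G2/M phase genes fell in 49 of 49 cases from E18.5 to P1 (median -1.74) and 39 of them rose from P1 to 1W, and both changes share the P1 libraries. With the sex term, which takes the effect of sex as equal at all ages, 98% were called lower at P1. Of the risers, 82.1% were called at 1W with that term. A sex effect equal at all ages thus does not account for most of the pattern. All 3 P1 libraries carried Y transcripts without Xist, so an effect of sex particular to P1 is left open. Dilution by RNA of other cells would lower the cardiomyocyte, endothelial, fibroblast and mural markers as well, and their median change was 0.21. More RNA from those marked cell types themselves would not lower their markers, so this median says nothing about that. Without 1 P1 library, at least 98% were still called lower at P1, and at least 76.9% of the risers at 1W, which leaves the part of single libraries in the rise undecided. A lower share of dividing cells at P1 may underlie the dip, which transcripts alone cannot show.

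The sex term was chosen after the data were seen, but no test of this part after its own result. Rules written beforehand would have decided the tests of mitochondrially encoded genes and of the 5 sex-linked genes. Those rules were set aside for the reasons given below. In 8W against P1, sex-linked transcripts and age go together, so the sex term takes its estimate from the other ages. With that estimate 88.8% of the calls kept their direction, so a sex effect equal at all ages does not account for most of them, and one particular to these ages is left open. Without mitochondrially encoded and globin genes 99.6% of the calls of other genes kept their direction, but TMM scaling hardly moved with them (12891 and 12907 calls), so this decides nothing. Of Xist and the 4 genes of the Y chromosome, 0 of 5 were called with the term, which is coded from these same genes and takes up their difference, so this decides nothing either. Their log2 changes ± SE before and after were 7.17 ± 3.09 and -2.85 ± 1.34 for Xist, -13.75 ± 5.43 and -5.49 ± 7.05 for Ddx3y, -13.52 ± 5.43 and -5.29 ± 7.14 for Kdm5d, -13.35 ± 5.3 and -5.19 ± 6.96 for Eif2s3y and -13.1 ± 5.37 and -4.99 ± 7.25 for Uty.

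The test of sex in this part was chosen only after its result was seen, in place of an earlier bound that was missed (a G2/M phase score of 0.28, the lowest at 1W, against 0.27 found). Replicate 3 of 2W had lower scores (S phase -1.66, G2/M phase -2.18) than the other 2W libraries (S phase -0.73 and -0.03, G2/M phase -0.26 and 0.27), and the 4W libraries had G2/M phase scores of -3.16 to -2.98. A later stage of that library would bring it nearest to 4W in most lists, and it was nearest in 1 of 8. In several lists the 2W libraries were nearly tied, as in adult sarcomere (1.1, 1.07 and 1.05), so the rank there decides little. The 1 list was fatty acid oxidation, whose 4W mean (1.28) lay between the 1W mean (1.06) and the 2W scores (1.42 to 1.49). Nearest to 4W was thus also nearest to 1W in that list. The other library with the same sex-linked transcripts scored 0.27 for G2/M phase, so sex alone does not account for the low scores, which rests on that 1 library. The total count of replicate 3 was 93.3% of the lower of the other totals, so depth does not account for them either. The cause of the low scores is left open.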
